A study of Homo sapiens with 27 samples.

How the data were processed

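RNA was measured in 27 libraries of human fibroblasts, 21 of H9F and 6 of HCF, made per the labels from total RNA isolated with TRI Reagent and prepared with a NEBNext Ultra Directional kit, which marks the strand. The reprogramming constructs named in the labels were MGT, a microRNA plasmid, and TBX20 or an empty vector (EV); the labels do not say which samples received the microRNA plasmid. The deposited values are raw read counts per Ensembl gene ID, which the authors made with STAR 2.5.1b and genome build hg19 per the submitters' processing notes, and the notes also name DESeq2 with the version 3.11. The counting tool, the annotation, the strand setting and the treatment of multi-mapping reads are not given in the sources used here. The values were checked to be whole numbers with different totals per library, from 11896728 to 27420248 in H9F and from 14614527 to 17320487 in HCF, and columns of other samples numbered 0. Gene positions are not printed.

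Samples were placed in 7 H9F groups and 2 HCF groups of 3 libraries each from the labels, and the replicate number was not taken as a pairing. Across genes, the residuals of libraries with the same number correlated at −0.036 to 0.11, and not every library best matched the one with its own number, so the number entered a model as an alternative, the replicate block. Symbols were assigned from the Ensembl IDs with a GENCODE annotation, to 45038 of 48162 IDs in H9F and 51996 of 57905 in HCF, and 47740 IDs stood in both tables. In HCF, 2 IDs without a symbol held 0.403% to 3.15% of a library's counts. Genes of the Y chromosome and X inactivation were left out (444 and 474 IDs).

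Counts were analysed with edgeR 4.0.16 in R 4.3.3. TMM factors and filterByExpr with a min.count of 10 left 18584 genes in H9F, 13979 of them protein-coding, and 15142 in HCF. All 21 H9F libraries entered 1 quasi-likelihood fit with a mean per group (14 residual degrees of freedom), and the 6 HCF libraries another (4 residual degrees of freedom). Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, for TBX20 against EV at days 3, 9 and 14 and in HCF, for EV at each day against day 0, and for the difference of the TBX20 effect between successive days. The SE of a log2 fold change was its size divided by the square root of F. CPM values use TMM-scaled library sizes.

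Gene lists, 26 in all, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. A list needed 5 tested members. The lists were reprogramming factors, sarcomere, calcium handling and ion channels, cardiac transcription factors and natriuretic peptides, nuclear oxidative phosphorylation, mitochondrially encoded genes, tricarboxylic acid cycle, fatty acid oxidation, glycolysis, fibroblast and extracellular matrix, TGF-beta and myofibroblast, cell cycle, interferon response, inflammatory cytokines, p53 and senescence, skeletal muscle, smooth muscle, endothelial, epithelial and epicardial, neuronal, pluripotency, atrial, ventricular, pacemaker, ribosomal proteins and histones. Some lists share members, such as ACTA1 in sarcomere and skeletal muscle and NPPA in the atrial and peptide lists. GJA5, CCL5, MYLPF, PECAM1, NEFL, H3C2 and H4C2 had no matching symbol and were not analysed here. Medians are given for lists without a member in a group at 0.

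Named genes followed a rule. For each comparison of TBX20 with EV and of EV with day 0 they were the 6 largest rises and 6 largest falls by fitted log2 fold change among called genes with a mean of at least 5 CPM in the higher group, CPM ranges that did not overlap and a symbol that is not a clone, accession or non-coding identifier. To these the rule added the 4 reprogramming factors, up to 3 members of each list with the smallest p, the 6 genes called in the same direction in all 4 TBX20 comparisons with the largest smallest change, and the 3 largest changes each way of each day difference. A gene that the rule named is not reported here. Comparisons, tests, lists, the rule and most alternatives were chosen before the data were examined. Overlaps of calls were tested with Fisher's exact test, one-sided, among genes tested in both comparisons, with Benjamini-Hochberg adjustment.

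Where a group had no counts of a gene, a lower bound of the fold was computed against a floor of 3 counts per library. With 1 to 3 counts, the ratio of summed counts is given with its 95% Clopper-Pearson interval. Intervals and floors cover counting error only.

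Alternatives chosen beforehand were RLE factors, no filter on low counts, the replicate block, the mitochondrially encoded genes and reprogramming factors left out, the DESeq2 1.42.0 Wald test, a fit of the compared libraries alone, each replicate left out in turn, a fold of at least 2 in addition, camera with an estimated correlation, camera with the replicate block, and fry. Those added after seeing the data left out the 2 H9F libraries that stood apart (day 9 EV replicate 1 and day 14 TBX20 replicate 2), the day 14 libraries, or HCF EV replicates 2 and 3, left out each replicate in the list tests, and ran the list tests on the day differences. With HCF EV replicate 1 as the one control, the spread came from the TBX20 libraries alone, and the lone library was assumed to vary like them.

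The gene test was tested on simulated data with 200 genes changed by a known fold. For TBX20 against EV at day 14, over 17763 genes, it called 32 of 64 genes changed 1.5-fold, 40 of 66 changed 2-fold and 53 of 64 changed 4-fold, and 7 of 17569 unchanged genes. In HCF, over 14865 genes, it called 15 of 67, 51 of 66 and 56 of 62, and 9 of 14670 unchanged genes. For the difference of the effect between days 14 and 9, it called 17 of 64, 34 of 66 and 49 of 64, and 9 unchanged genes. Figures were drawn with Python 3.11.15, matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.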

Results

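The series asks how adding the heart transcription factor TBX20 to a direct cardiac reprogramming mix alters gene expression in human fibroblasts, with contractility and energy metabolism as its stated subjects. The mix, MGT, holds MEF2C, GATA4 and TBX5, and cells given MGT with an empty vector (EV) were the controls on the same day. The data are gene counts from 27 RNA-seq libraries. Of these, 21 came from H9F cells, fibroblasts derived from the H9 human embryonic stem cell line, taken at day 0 before reprogramming and at days 3, 9 and 14 with EV or TBX20. The remaining 6 came from HCF, primary human ventricular fibroblasts, with EV or TBX20, and their labels give no day. Each group held 3 libraries, which the series design calls biological replicates. Total counts ran from 11896728 to 27420248 per H9F library and from 14614527 to 17320487 per HCF library.

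In what follows, a gene rose or fell if it passed an adjusted p under 0.05 in an edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Levels are mean CPM (counts scaled by library size) ± SD and changes are log2 fold changes ± SE, with n = 3 libraries in each group. TNNT2, ACTC1, MYH6, MYH7, MYBPC3, MYL7, MYL4, NPPA, NPPB, ATP2A2, TTN, CKM, COL1A1, PLN, SLN, GJA1 and LDB3 are followed across comparisons, a choice made after their values were seen. Reads of MYH6 and MYH7, of ACTA1 and ACTC1, of TNXB and its partial copy, and of the IFIT, histone and ribosomal protein genes can be shared with near-identical copies, so the share of each copy is uncertain.

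A few libraries stood apart from their groups. Replicate 1 of the day 9 EV group had counts for 18985 genes, against 24991 and 25142 in its partners, and correlated with them at 0.957 across genes. Replicate 2 of the day 14 TBX20 group correlated with its partners at 0.971 and 0.972. In HCF, EV replicate 1 correlated with EV replicates 2 and 3 at 0.977 and 0.973, and TBX20 replicates correlated with one another at 0.988 to 0.989. The 2 IDs without a symbol named above held 3.153% of counts in HCF TBX20 replicate 2, against 0.4034% and 0.4217% in its partners and 1.276% to 2.562% with EV. Genes are not independent replicates, so these correlations describe the libraries and test nothing.

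TBX20 (ENSG00000164532) reached 9529 ± 220 CPM at day 3, 9824 ± 261 CPM at day 9 and 10220 ± 998 CPM at day 14, and 8493 ± 356 CPM in HCF. The EV controls held 0.0820 ± 0.0990, 0.257 ± 0.223 and 0.333 ± 0.0956 CPM on the 3 days, and 3.783 ± 1.504 CPM in HCF. Counts cannot tell the introduced copy from the cell's own gene. Changes of the MGT factors did not pass the test at day 3 (log2 0.26 for GATA4, 0.13 for TBX5, 0.04 for MEF2C) or at day 9 (log2 −0.20, −0.08 and −0.11). Nor did they in HCF (log2 −0.01 to 0.19), but without HCF EV replicate 1 all 3 passed as higher (log2 0.50 for MEF2C, 0.33 for GATA4 and 0.19 for TBX5). Without TBX20 replicate 1, GATA4 passed as higher at day 3 (log2 0.38). At day 14 all 3 fell with TBX20. TBX5 went from 2437 ± 156 to 1579 ± 71.1 CPM (log2 −0.63 ± 0.09, adjusted p = 1.9e-06), MEF2C from 1545 ± 84.3 to 1079 ± 166 CPM (log2 −0.52 ± 0.10) and GATA4 from 1509 ± 114 to 1001 ± 61.4 CPM (log2 −0.59 ± 0.12). Of the reprogramming factor list, 1 of 4 members was therefore higher at days 3 and 9 and in HCF, and 1 was higher and 3 lower at day 14.

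By day 3, heart genes had risen in cells given MGT with EV, several of them nearly silent at day 0. MYL7, the atrial myosin light chain, rose from 0.198 to 93.7 ± 4.59 CPM (log2 8.94 ± 0.35). NPPB, which encodes a natriuretic peptide, rose from 0.126 to 129 ± 7.30 CPM (log2 9.90 ± 0.35). ANKRD1, a stress-responsive sarcomere protein, rose from 30.7 ± 2.28 to 1383 ± 32.3 CPM (log2 5.49 ± 0.09). NEBL and TNNC1 had 2 counts each at day 0 and 1764 and 2225 counts at day 3, ratios of 913 (95% counting interval 252 to 7543) and 1151 (318 to 9513). In the same cells MMP3, a matrix-degrading enzyme, fell from 187 ± 5.72 to 12.2 ± 0.30 CPM (log2 −3.93 ± 0.19), and IGF2, SCG5 and CDK15 fell by log2 −4.01, −4.42 and −4.57. In all, 3876 of 18584 genes rose and 3422 fell.

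At day 3 the sarcomere list had 19 higher, 6 lower and 20 not called of 45, and 19 and 6 adjusted over the list alone (camera adjusted p = 3.22e-05). TNNT2 and ACTC1 were among the higher members, at log2 8.54 and 5.84. Of 25 interferon response genes, 25 rose (25 adjusted over the list alone, adjusted p = 3.65e-19), among them IFI6 from 9.05 ± 0.85 to 799.5 ± 144 CPM. Atrial genes had 7 higher and 1 lower of 11 (adjusted p = 0.000227), and cell cycle genes 17 higher and 2 lower of 38 (adjusted p = 0.0385), with RRM2 rising from 36.8 to 115 CPM. With an estimated correlation none of these 4 calls held: adjusted p = 0.0795 for sarcomere, 0.111 for interferon, 0.111 for atrial and 0.399 for cell cycle with an estimated correlation. The cell cycle call also ended without day 0 replicate 2 (0.0568), day 0 replicate 3 (0.0546) or EV replicate 1 (0.0507).

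At day 9, TNNT2, cardiac troponin T, stood at 1275 ± 197 CPM with EV against 0.159 at day 0 (log2 12.86 ± 0.27), and MYL7 at 1137 ± 207 CPM (log2 12.55 ± 0.33). GJA1, the main ventricular gap junction protein, rose from 139 ± 7.32 to 2229 ± 90.6 CPM (log2 4.002 ± 0.08), and PLN, which restrains the calcium pump of the sarcoplasmic reticulum, from 0.121 to 335 ± 23.1 CPM (log2 11.49 ± 0.22). MYL4 was at least 244.5-fold, SLN at least 97.0-fold and MYH7 at least 21.25-fold higher than day 0, where no library had a count. MMP3 and IL11 fell by log2 −6.24 ± 0.22 and −5.45 ± 0.18. Genes called numbered 5396 higher and 5457 lower.

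Of the day 9 lists, sarcomere had 37 higher and 4 lower of 45 (38 and 4 adjusted over the list alone, adjusted p = 5.60e-18), calcium handling and ion channels 25 higher and 5 lower of 39 (adjusted p = 6.66e-06), and atrial genes 10 higher and 1 lower of 11 (adjusted p = 4.38e-07). Cell cycle genes went the other way, 36 lower and 1 higher of 38, with CDC20 falling from 55.3 to 7.80 CPM and a median log2 of −2.14 (adjusted p = 2.27e-14). These 4 calls held with an estimated correlation (adjusted p = 0.0113 or smaller). Interferon genes rose (23 of 25, adjusted p = 4.28e-08, but 0.203 with an estimated correlation). So did fatty acid oxidation (18 higher and 3 lower of 32, adjusted p = 0.000277, and 0.0998 with an estimated correlation) and histones (10 of 11, adjusted p = 0.000587, and 0.0998). Cardiac transcription factors and peptides rose too (15 higher and 6 lower of 27, adjusted p = 0.0147, and 0.114 with an estimated correlation). Glycolysis fell (19 lower and 5 higher of 26, adjusted p = 0.000211, and 0.206 with an estimated correlation), with the glucose transporter SLC2A1 going from 447 to 80.9 CPM. Ribosomal proteins fell too (31 lower and 1 higher of 39, adjusted p = 7.67e-06, and 0.480 with an estimated correlation).

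The mitochondrially encoded, skeletal muscle and ventricular lists also passed at day 9 (8 of 13, 7 of 18 and 7 of 11 higher, adjusted p = 0.0445, 0.0439 and 0.0445), but not with an estimated correlation (adjusted p = 0.665, 0.0998 and 0.0998 with an estimated correlation). The mitochondrially encoded genes held 7.56% of counts in day 9 EV replicate 1 and 5.71% and 5.45% in its partners, and without that library their adjusted p was 0.140. That call also ended without day 0 replicate 2 (0.05265) or 3 (0.0524), the skeletal muscle call without day 0 replicate 2 (0.0527) or EV replicate 3 (0.05005), and the ventricular call without EV replicate 1 (0.0580).

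By day 14, sarcomere genes had risen with EV and cell cycle genes had fallen. MYH7, the slow cardiac myosin, stood at 1770 ± 48.0 CPM, at least 10620-fold above a day 0 without counts, and SLN, a regulator of the calcium pump, at 666 ± 47.7 CPM, at least 3997-fold. TNNT2 reached 4442 ± 332 CPM (log2 14.66 ± 0.27) and ACTC1, cardiac actin, 2922 ± 62.6 CPM (log2 11.28 ± 0.16). NPPA, atrial natriuretic peptide, reached 1756 ± 412 CPM (log2 11.15 ± 0.30). Fibronectin (FN1) fell from 17120 ± 416 to 826 ± 90.5 CPM (log2 −4.37 ± 0.10) and the collagenase MMP1 from 5164 ± 83.1 to 15.8 ± 2.45 CPM (log2 −8.36 ± 0.14). TOP2A, a topoisomerase of dividing cells, fell from 164 to 3.84 CPM (log2 −5.39 ± 0.16). In total 6133 genes rose and 6127 fell.

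The day 14 lists divided in the same way. Sarcomere had 40 higher and 2 lower of 45 (40 and 3 adjusted over the list alone, adjusted p = 7.31e-20). Calcium handling had 29 higher and 5 lower of 39 (adjusted p = 7.99e-08), and fatty acid oxidation 25 higher and 3 lower of 32 (adjusted p = 4.63e-06). Skeletal muscle had 15 higher of 18 (adjusted p = 1.01e-05), atrial 8 higher and 2 lower of 11 (adjusted p = 6.44e-05) and ventricular 8 higher and 2 lower of 11 (adjusted p = 0.00758). Cell cycle had 36 lower of 38 (median log2 −2.66, adjusted p = 1.71e-13). These 7 calls held with an estimated correlation (adjusted p = 0.0348 or smaller). Nuclear oxidative phosphorylation genes had 62 higher and 5 lower of 78 (median log2 0.98, adjusted p = 1.05e-06), with SDHA, a subunit of complex II, rising from 139 ± 3.98 to 325.5 ± 9.12 CPM. All 13 mitochondrially encoded genes rose (median log2 1.77, adjusted p = 5.14e-05), and their share of counts was 10.48% to 11.55% in day 14 EV libraries against 3.50% to 3.59% at day 0. Tricarboxylic acid cycle genes had 19 higher and 3 lower of 25 (adjusted p = 0.000127), and matrix genes 28 lower and 8 higher of 38 (median log2 −1.43, adjusted p = 1.22e-05). With an estimated correlation, adjusted p = 0.396, 0.303, 0.303 and 0.0825 for these 4 lists. Interferon genes (15 higher and 1 lower of 25, adjusted p = 0.0055), histones (7 higher of 11, adjusted p = 0.00366) and inflammatory cytokines (12 lower and 2 higher of 16, adjusted p = 0.00479) passed too, with adjusted p = 0.4996, 0.166 and 0.206 with an estimated correlation.

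The labels do not say whether the days were processed together, so a batch difference can be part of a change between days. Day 0 cells were taken before reprogramming, and no group held EV without MGT. A change from day 0 therefore also holds the vectors and the time in culture, which cannot be told apart from MGT. The lists not named for a given day did not pass the list test on that day. When the 2 H9F libraries that stood apart were left out, mitochondrially encoded genes passed as lower at day 3 (0.0412), and TGF-beta and ribosomal genes as lower at day 14 (0.0474 each). Ribosomal genes also passed at day 14 without EV replicate 2 (0.0358). With an estimated correlation the adjusted p of these 3 calls was 0.9235, 0.370 and 0.690, and with fry 0.0688, 8.59e-07 and 0.00760.

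**Figure D1:**
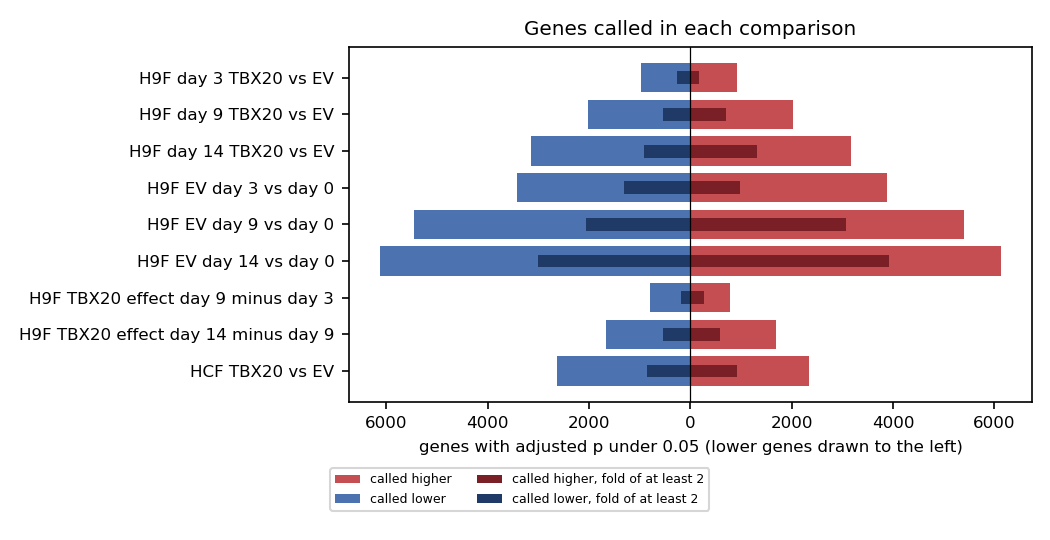
Genes called higher or lower at an adjusted p under 0.05 in each comparison, with the part that also changed at least 2-fold (bars, number of genes, n = 3 libraries per group). With TBX20 the counts were 918 and 981 at day 3, 2026 and 2012 at day 9, 3180 and 3148 at day 14, and 2346 and 2623 in HCF.

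At day 3, LDB3, AKAP6, SYNPO, TNXB and DIO2 were among the genes that rose with TBX20, and the natriuretic peptide genes NPPA and NPPB among those that fell. LDB3, a Z-disc protein, rose from 4.86 ± 0.26 to 23.5 ± 2.00 CPM (log2 2.28 ± 0.12, adjusted p = 9.5e-14). AKAP6, a scaffold of the muscle nuclear envelope, rose from 13.6 ± 1.05 to 59.1 ± 9.69 CPM and SYNPO, an actin-associated protein, from 9.23 ± 0.95 to 46.7 ± 7.15 CPM. TNXB, a matrix glycoprotein, went from 7.32 ± 1.04 to 54.3 ± 6.54 CPM (log2 2.89 ± 0.15) and DIO2, which activates thyroid hormone, from 11.9 ± 1.05 to 61.6 ± 6.40 CPM. NPPB fell from 129 ± 7.30 to 9.79 ± 1.84 CPM (log2 −3.74 ± 0.19) and NPPA from 11.1 ± 0.733 to 0.898 ± 0.112 CPM (log2 −3.62 ± 0.33). NEBL, a nebulin-related Z-disc protein, fell from 33.5 ± 2.84 to 2.26 ± 0.31 CPM (log2 −3.89 ± 0.12). IGFN1, SERPINB2, BMPER and NTM fell by log2 −5.54, −5.24, −3.80 and −3.63.

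The sarcomere list had 10 higher, 7 lower and 28 not called of 45 at day 3 (11 and 7 adjusted over the list alone) and did not pass the list test (adjusted p = 0.0693), though it did without EV replicate 1 (0.0227). The adjusted p was 0.408 with an estimated correlation, and fry pointed downward (0.911). DES and ACTA1 rose by log2 1.62 and 1.14, while ANKRD1, CSRP3 and TNNT2 fell by log2 −2.51, −3.44 and −2.30. Cardiac transcription factors and peptides had 9 lower, 1 higher and 17 not called of 27 (adjusted p = 3.25e-05, and adjusted p = 0.0360 with an estimated correlation), with TBX18 and BMP2 falling beside both peptides. Atrial genes had 6 lower and 2 higher of 11 (adjusted p = 0.00257, and adjusted p = 0.214 with an estimated correlation), with MYL7 at 35.1 ± 10.2 against 93.7 ± 4.59 CPM. Smooth muscle markers had 7 higher and 1 lower of 14 (adjusted p = 0.00257, and adjusted p = 0.0550 with an estimated correlation), including RGS5 and SYNPO2 at log2 1.89 and 1.07. Calcium handling had 3 higher and 6 lower of 39 and did not pass. In that list GJA1 fell from 306 ± 5.50 to 119 ± 2.97 CPM (log2 −1.36 ± 0.07) and JPH2 rose from 4.19 to 10.4 CPM. Skeletal muscle markers had 3 higher of 18, ventricular genes 1 lower of 11 and pacemaker genes 3 lower of 12, and none of these lists passed.

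Interferon genes had 6 higher and 0 lower of 25 at day 3, 9 adjusted over the list alone, with a median log2 of 0.51 (adjusted p = 0.0025, and adjusted p = 0.630 with an estimated correlation), and IFIT3 went from 180 ± 25.5 to 377 ± 82.9 CPM. Fatty acid oxidation had 4 higher and 1 lower of 32 (adjusted p = 0.0126, and adjusted p = 0.408 with an estimated correlation), led by PPARGC1A, a regulator of mitochondrial genes, at log2 1.52. Matrix genes had 12 lower and 6 higher of 38 (adjusted p = 0.00944, and adjusted p = 0.408 with an estimated correlation), with the collagen cross-linker LOX falling from 770 to 233 CPM. Inflammatory cytokines had 6 lower and 2 higher of 16 (adjusted p = 0.00493, and adjusted p = 0.332 with an estimated correlation), with VCAM1 falling from 42.2 to 7.96 CPM. Ribosomal proteins had 0 called of 39 and oxidative phosphorylation 1 lower of 78, yet both lists passed as lower (median log2 −0.12 and −0.10, adjusted p = 0.00257 and 0.0381). With an estimated correlation they did not (adjusted p = 0.748 and 0.795 with an estimated correlation).

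Mitochondrially encoded genes (0 called of 13), tricarboxylic acid cycle (1 lower of 25), glycolysis (2 higher and 5 lower of 26) and TGF-beta and myofibroblast genes (7 higher and 4 lower of 27) did not pass the list test. Nor did cell cycle (1 lower of 38), p53 and senescence (3 higher of 20), endothelial (1 lower of 11), epithelial (3 higher and 3 lower of 12), neuronal (2 higher and 1 lower of 11), pluripotency (0 of 9) or histone genes (0 of 11). The median, mean and test differed in sign for calcium handling, glycolysis, cell cycle, ventricular and pacemaker genes, none of which passed. Without TBX20 replicate 3 the oxidative phosphorylation adjusted p was 0.826, and without EV replicate 2 it was 0.134, while the inflammatory call ended without EV replicate 2 (0.0573). The count of higher genes was 540 without TBX20 replicate 3 and 602 without EV replicate 1, against 918 with all libraries, and 1433 when the 2 H9F libraries of days 9 and 14 that stood apart were left out of the fit.

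At day 9, most called sarcomere genes rose with TBX20, while GJA1 and PLN fell. MYBPC3, cardiac myosin binding protein C, rose from 2.30 ± 0.42 to 88.5 ± 1.91 CPM (log2 5.26 ± 0.12, adjusted p = 3.5e-22), and MYH6, the fast cardiac myosin, from 10.4 ± 1.70 to 274 ± 24.0 CPM (log2 4.72 ± 0.12, adjusted p = 2.0e-19). LDB3 went from 106 ± 4.59 to 606 ± 14.5 CPM (log2 2.51 ± 0.09). PLN fell from 335 ± 23.1 to 49.4 ± 4.69 CPM (log2 −2.76 ± 0.11) and GJA1 from 2229 ± 90.6 to 475 ± 27.4 CPM (log2 −2.23 ± 0.07). Outside the muscle lists, the rule for named genes took rises of NTS, a neuropeptide, DOK5, OSTN and SLC17A7 (log2 5.40, 4.87, 4.84 and 4.78) and falls of NTM, PLEKHA7, CGNL1, CTSV, BMP6 and SLC16A9 (log2 −6.45 to −5.19).

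Of 45 sarcomere genes, 27 rose, 10 fell and 8 were not called at day 9 (28 and 10 adjusted over the list alone), and the list passed with either correlation (adjusted p = 4.47e-07, and adjusted p = 0.0119 with an estimated correlation). Skeletal muscle markers had 8 higher and 0 lower of 18, 10 and 1 adjusted over the list alone (adjusted p = 7.73e-06, and adjusted p = 0.00309 with an estimated correlation), with TNNT1, slow skeletal troponin T, rising from 3.895 to 51.0 CPM. Cardiac transcription factors and peptides had 14 lower and 5 higher of 27 (adjusted p = 2.80e-05, and adjusted p = 0.0194 with an estimated correlation), with TBX18, HEY1, BMP2 and NPPA falling. TNNT2 and ATP2A2, the calcium pump, fell by log2 −1.02 ± 0.13 and −0.96 ± 0.06, while ACTC1, CKM and MYH7 rose by log2 2.13, 2.90 and 2.30. MYL4, an atrial myosin light chain, rose from 40.8 ± 6.27 to 192 ± 22.6 CPM, and SLN fell from 16.2 to 2.56 CPM. Atrial genes had 3 higher and 5 lower of 11, ventricular genes 4 higher and 3 lower of 11, pacemaker genes 1 higher and 4 lower of 12 and calcium handling 14 higher and 10 lower of 39, and none of these lists passed. TTN (log2 −0.12) did not pass the test.

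Interferon genes had 22 higher and 0 lower of 25 at day 9 with a median log2 of 1.72 (adjusted p = 2.85e-11, and adjusted p = 0.201 with an estimated correlation), with IFIT3 at 272 ± 53.2 against 82.1 ± 13.3 CPM. In energy metabolism, tricarboxylic acid cycle genes had 14 higher and 0 lower of 25, 16 adjusted over the list alone (median log2 0.27, adjusted p = 0.000188, and adjusted p = 0.347 with an estimated correlation), including MPC2, a mitochondrial pyruvate carrier, MDH1 and DLD. Fatty acid oxidation had 15 higher and 2 lower of 32 (adjusted p = 0.000557, and adjusted p = 0.201 with an estimated correlation), with the fatty acid transporter CD36 rising from 131 ± 11.3 to 289 ± 19.9 CPM and FABP3 from 99.3 to 243 CPM. Glycolysis had 13 higher and 2 lower of 26 (adjusted p = 0.00501, and adjusted p = 0.347 with an estimated correlation), with the muscle enolase ENO3 rising from 5.02 to 58.0 CPM and SLC2A1 falling by log2 −1.20. Oxidative phosphorylation had 15 higher and 0 lower of 78, 13 adjusted over the list alone (median log2 0.24, adjusted p = 0.00223, and adjusted p = 0.554 with an estimated correlation), with ATP5F1B at 694 ± 55.1 against 494 ± 52.2 CPM. The mean log2 CPM of this list was 4.48 in day 9 EV replicate 1 and 4.93 and 4.85 in its partners, and without replicate 1 the adjusted p was 0.136. The glycolysis adjusted p was 0.0551 when the 2 H9F libraries that stood apart were left out.

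Matrix genes had 22 lower and 9 higher of 38 at day 9 (median log2 −0.30, adjusted p = 0.000103, and adjusted p = 0.201 with an estimated correlation), with thrombospondin 2 (THBS2) falling from 1992 to 508 CPM and POSTN by log2 −2.00. Ribosomal proteins had 19 lower and 0 higher of 39, 24 adjusted over the list alone (median log2 −0.25, adjusted p = 1.39e-06, and adjusted p = 0.355 with an estimated correlation). TGF-beta and myofibroblast genes (9 higher and 8 lower of 27), cell cycle (2 higher and 9 lower of 38), inflammatory cytokines (1 higher and 4 lower of 16) and p53 and senescence (2 higher and 4 lower of 20) did not pass. Nor did smooth muscle (5 higher and 5 lower of 14), endothelial (3 lower of 11), epithelial (5 higher and 2 lower of 12), neuronal (3 higher and 1 lower of 11), pluripotency (2 higher of 9), histone (1 higher of 11) or mitochondrially encoded genes (2 lower of 13). Epithelial genes passed as higher without EV replicate 2 (0.0185), EV replicate 3 (0.0203) or TBX20 replicate 2 (0.0389), and pluripotency genes without TBX20 replicate 2 (0.0213) or 3 (0.0180). The calls of the pluripotency genes LIN28A and DNMT3B ended without TBX20 replicate 1 (adjusted p = 0.4463 and 0.2437). Mitochondrially encoded genes passed as lower without EV replicate 2 (0.0264), EV replicate 3 (0.0137) or TBX20 replicate 3 (0.0422), and cell cycle genes without TBX20 replicate 3 (0.0453). With an estimated correlation the adjusted p was 0.380, 0.347, 0.554 and 0.347 for these 4 lists, and with fry 0.00153, 0.00611, 0.148 and 0.0124. For the TGF-beta and endothelial lists the median was above 0 and the mean and test below it. Among members of these lists, KRT8 and KRT18, keratins of simple epithelia, rose by log2 1.81 and 1.24, and KDR, a vascular growth factor receptor, fell by log2 −3.93.

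**Figure D2:**
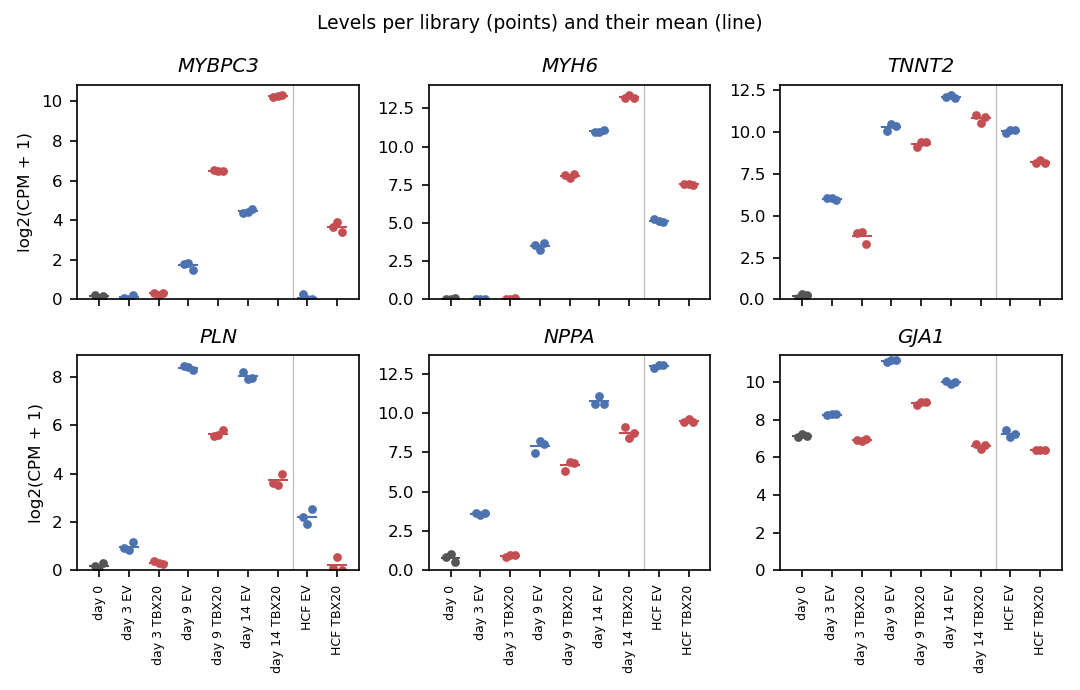
Levels of MYBPC3, MYH6, TNNT2, PLN, NPPA and GJA1 in each library, as log2 of CPM plus 1, by group (points; lines, group means; 3 libraries per group). MYBPC3 was higher and PLN and GJA1 lower with TBX20 than with EV in H9F at days 9 and 14.

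At day 14, the genes that TBX20 raised included those of both cardiac and skeletal muscle. MYBPC3 reached 1244 ± 41.4 CPM against 20.75 ± 1.496 (log2 5.90 ± 0.10, adjusted p = 3.3e-25). CKM, muscle creatine kinase, reached 254 ± 10.5 against 12.2 ± 1.36 CPM (log2 4.38 ± 0.13) and RYR1, the skeletal muscle calcium release channel, 489 ± 82.4 against 11.1 ± 2.30 CPM (log2 5.45 ± 0.16). PLN fell from 262 ± 26.5 to 12.3 ± 2.33 CPM (log2 −4.41 ± 0.13) and SLN from 666 ± 47.7 to 42.2 ± 2.66 CPM (log2 −3.98 ± 0.15). GJA1 fell from 1010 ± 53.3 to 95.4 ± 9.07 CPM (log2 −3.405 ± 0.08). Outside muscle, PADI2, which converts arginine to citrulline in proteins, rose from 7.37 ± 0.47 to 911 ± 46.0 CPM and the growth factor IGF2 from 2.74 ± 0.40 to 325 ± 41.2 CPM. STUM, CTSV, ZNF385B, NTM and RGS16 fell by log2 −7.28 to −6.44.

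Of 45 sarcomere genes, 25 rose, 12 fell and 8 were not called at day 14 (adjusted p = 0.00179, and adjusted p = 0.143 with an estimated correlation). MYPN, MYH6 and TTN rose by log2 3.14, 2.24 and 1.02, and TNNT2 and MYL7 fell by log2 −1.29 and −0.78. Skeletal muscle markers had 13 higher and 2 lower of 18, 14 and 2 adjusted over the list alone (adjusted p = 4.24e-05, and adjusted p = 0.00463 with an estimated correlation), with the embryonic myosin MYH3 at 227 ± 21.2 against 13.6 ± 1.13 CPM and TNNT3 at 193.5 against 8.67 CPM. Atrial genes had 7 lower and 2 higher of 11 (adjusted p = 0.0108, and adjusted p = 0.291 with an estimated correlation), with NPPA at 439.5 ± 101 against 1756 ± 412 CPM. Cardiac transcription factors and peptides had 15 lower and 5 higher of 27 (adjusted p = 0.00589, and adjusted p = 0.143 with an estimated correlation), with ISL1 and HEY1 falling by log2 −3.79 and −2.53. Calcium handling had 18 higher and 11 lower of 39 without passing, and ATP2A2 fell by log2 −1.05 ± 0.06. Ventricular genes (3 higher and 4 lower of 11) and pacemaker genes (3 higher and 4 lower of 12) did not pass.

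Interferon genes had 20 higher and 0 lower of 25 at day 14 with a median log2 of 1.43 (adjusted p = 1.42e-05, and adjusted p = 0.537 with an estimated correlation), including XAF1 and IFI27 at log2 3.49 and 3.31. Epithelial markers had 5 higher and 0 lower of 12 (adjusted p = 0.0172, and adjusted p = 0.537 with an estimated correlation), with KRT8 rising from 41.8 to 899 CPM. With all libraries no energy metabolism list passed at day 14. Oxidative phosphorylation had 16 lower and 1 higher of 78 (median log2 −0.14, adjusted p = 0.0903), and SDHA fell from 325.5 to 192 CPM. That list passed as lower without TBX20 replicate 1 (0.0136), EV replicate 1 (0.0401) or EV replicate 3 (0.0202), and went further from passing without TBX20 replicate 2 (0.5224), EV replicate 2 (0.6033) or the 2 libraries that stood apart (0.4687). The adjusted p was 0.978 with an estimated correlation and 0.211 with fry. Mitochondrially encoded genes had 2 lower of 13, and their share of counts was 7.66% in TBX20 replicate 2, which stood apart, and 10.84% and 9.73% in its partners. Without that library both calls, MT-ND2 and MT-CO2, ended (log2 −0.18 for each, adjusted p = 0.2502 and 0.2995). Tricarboxylic acid cycle had 3 higher and 7 lower of 25, fatty acid oxidation 10 higher and 9 lower of 32 and glycolysis 6 higher and 7 lower of 26, with ENO3 rising from 6.91 ± 1.04 to 349.8 ± 14.6 CPM and PDHA1, a subunit of pyruvate dehydrogenase, falling by log2 −1.12.

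Matrix genes had 19 higher and 13 lower of 38 at day 14 (median log2 0.21, adjusted p = 0.0859), with lumican (LUM) rising from 52.1 ± 1.07 to 321 ± 41.8 CPM and COL1A1 by log2 0.82 ± 0.08. The list passed as higher without TBX20 replicate 2 (0.0444) or EV replicate 1 (0.0462) and with fry (1.03e-05). It did not pass with an estimated correlation (0.720), and the adjusted p was 0.1498 without EV replicate 2 and 0.1016 without TBX20 replicate 3. TGF-beta and myofibroblast genes (12 higher and 9 lower of 27), cell cycle (12 higher and 3 lower of 38), inflammatory cytokines (1 higher and 2 lower of 16) and p53 and senescence (6 higher and 1 lower of 20) did not pass. Neither did smooth muscle (7 higher and 6 lower of 14), endothelial (4 higher and 3 lower of 11), neuronal (3 higher and 2 lower of 11), pluripotency (1 lower of 9), ribosomal (2 higher and 4 lower of 39) or histone genes (1 higher and 1 lower of 11). The median, mean and test differed in sign for glycolysis, inflammatory, smooth muscle, endothelial, neuronal, ventricular and histone genes, none of which passed.

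In HCF, MYH6 rose from 34.6 ± 2.46 to 184 ± 3.57 CPM with TBX20 (log2 2.41 ± 0.10, adjusted p = 4.7e-07), and UNC45B, a myosin chaperone, from 8.81 ± 1.47 to 92.0 ± 2.92 CPM. MYBPC3 went from 3 to 582 counts over the 3 libraries, a ratio of 172 (95% counting interval 58.4 to 834.5). NPPA fell from 8138 ± 590 to 723 ± 63.9 CPM (log2 −3.49 ± 0.19, adjusted p = 1.3e-06). SLN fell from 157 ± 40.9 to 11.6 ± 2.27 CPM (log2 −3.77 ± 0.225) and NEBL from 109.7 ± 19.8 to 3.01 ± 0.30 CPM (log2 −5.185 ± 0.18). LYVE1, a hyaluronan receptor, was at 15.6 ± 1.63 CPM with TBX20, at least 76.6-fold above EV libraries without counts. SCIN, an actin-severing protein, rose by log2 7.57 ± 0.36, and WNT2, GCHFR, CTSV, GSG1 and IRAG2 fell by log2 −5.68 to −4.79. In all, 2346 of 15142 genes rose and 2623 fell.

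Of 42 sarcomere genes in HCF, 17 rose, 13 fell and 12 were not called (18 and 15 adjusted over the list alone), and the list did not pass (adjusted p = 0.373). LDB3, MYL4 and TTN rose by log2 3.06, 1.99 and 0.99, and TNNT2 and MYL7 fell by log2 −1.865 and −2.49. Skeletal muscle markers had 7 higher and 1 lower of 15 (adjusted p = 0.00353, and adjusted p = 0.452 with an estimated correlation), with TNNT3 rising from 0.668 to 26.9 CPM. Atrial genes had 4 lower and 1 higher of 10 (adjusted p = 0.0310, and adjusted p = 0.452 with an estimated correlation), and cardiac transcription factors and peptides 9 lower and 2 higher of 22 (adjusted p = 0.0310, and adjusted p = 0.614 with an estimated correlation). Both calls ended without EV replicate 1 (adjusted p = 0.1375 and 0.152). Calcium handling had 12 higher and 9 lower of 35, with GJA1 falling by log2 −0.87 ± 0.11, and did not pass. RYR1, which is not on that list, rose from 1.29 to 26.0 CPM. Ventricular (1 higher and 3 lower of 10) and pacemaker genes (4 higher and 3 lower of 9) did not pass.

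Interferon genes had 22 higher and 0 lower of 25 in HCF, 23 adjusted over the list alone, with a median log2 of 2.34, and held with either correlation (adjusted p = 2.12e-16, and adjusted p = 0.0457 with an estimated correlation). BST2, a membrane tether of budding viruses, rose from 6.42 ± 0.46 to 75.2 ± 9.66 CPM (log2 3.55 ± 0.14). Cell cycle genes had 17 higher and 4 lower of 38 (median log2 0.58, adjusted p = 0.000121, and adjusted p = 0.614 with an estimated correlation), with TOP2A at log2 1.615 ± 0.20. Inflammatory cytokines had 13 higher and 2 lower of 24 (adjusted p = 0.00122, and adjusted p = 0.494 with an estimated correlation), TNFAIP6 at log2 1.54 and IL6 at log2 −1.03 among them. Matrix genes had 19 higher and 4 lower of 39 (median log2 0.56, adjusted p = 0.000121, and adjusted p = 0.614 with an estimated correlation), with LUM at 943 ± 22.3 against 354 ± 11.6 CPM. The mean log2 CPM of the matrix list was 8.08 in EV replicate 1 and 7.68 and 7.59 in EV replicates 2 and 3, and with replicate 1 as the one control the adjusted p was 0.1065.

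Ribosomal proteins had 38 lower and 0 higher of 39 in HCF (median log2 −0.94, adjusted p = 5.19e-07, and adjusted p = 0.663 with an estimated correlation), with RPL4 at 1288 ± 61.4 against 2500 ± 705 CPM. Oxidative phosphorylation had 40 lower and 0 higher of 76, 49 adjusted over the list alone (median log2 −0.58, adjusted p = 9.58e-07, and adjusted p = 0.716 with an estimated correlation), with COX5A at 101 ± 6.28 against 239.7 ± 64.2 CPM. With 1 library left out, ribosomal genes called lower numbered 39 without EV replicate 1 but 3 to 6 without any other library. For oxidative phosphorylation they numbered 68 and 6 to 12. The EV libraries differed in both lists. Mean log2 CPM of the oxidative phosphorylation genes was 6.01 in EV replicate 1 and 6.79 and 6.74 in replicates 2 and 3, and 5.955 to 6.07 with TBX20. For ribosomal proteins it was 9.33, 10.39 and 10.41 with EV and 9.15 to 9.28 with TBX20. With EV replicate 1 as the one control, the oxidative phosphorylation adjusted p was 0.755 and the ribosomal adjusted p 0.0145, with the spread taken from the TBX20 libraries alone.

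Mitochondrially encoded genes had 0 called of 13 in HCF and passed as higher (adjusted p = 0.0328, and adjusted p = 0.716 with an estimated correlation). They held 3.76% of counts in EV replicate 1, 2.40% and 1.83% in EV replicates 2 and 3, and 3.597% to 3.811% with TBX20. The call ended without EV replicate 2 (0.0789), EV replicate 3 (0.204) or TBX20 replicate 2 (0.0877). Tricarboxylic acid cycle (2 higher and 8 lower of 25), fatty acid oxidation (7 higher and 8 lower of 29), glycolysis (8 higher and 6 lower of 25), TGF-beta and myofibroblast (7 higher and 6 lower of 27) and p53 and senescence genes (2 higher and 4 lower) did not pass. Neither did smooth muscle (5 higher and 4 lower of 12), endothelial (5 higher and 2 lower of 11), epithelial (3 higher of 12), neuronal (3 higher and 1 lower of 8) or histone genes (4 higher and 1 lower of 7), though the histone list passed with EV replicate 1 as the one control (0.0145), against 0.716 with an estimated correlation. Of the pluripotency list 1 member was measured and was not called, and no list test was run. The median, mean and test differed in sign for calcium handling and TGF-beta genes. Without EV replicate 1, 4113 genes rose and 3988 fell in HCF. Without TBX20 replicate 3, 1469 rose and 1373 fell, and without TBX20 replicate 1, 1470 rose and 1462 fell. Without EV replicate 2 and without TBX20 replicate 2, 1628 and 1651 fell.

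**Figure D3:**
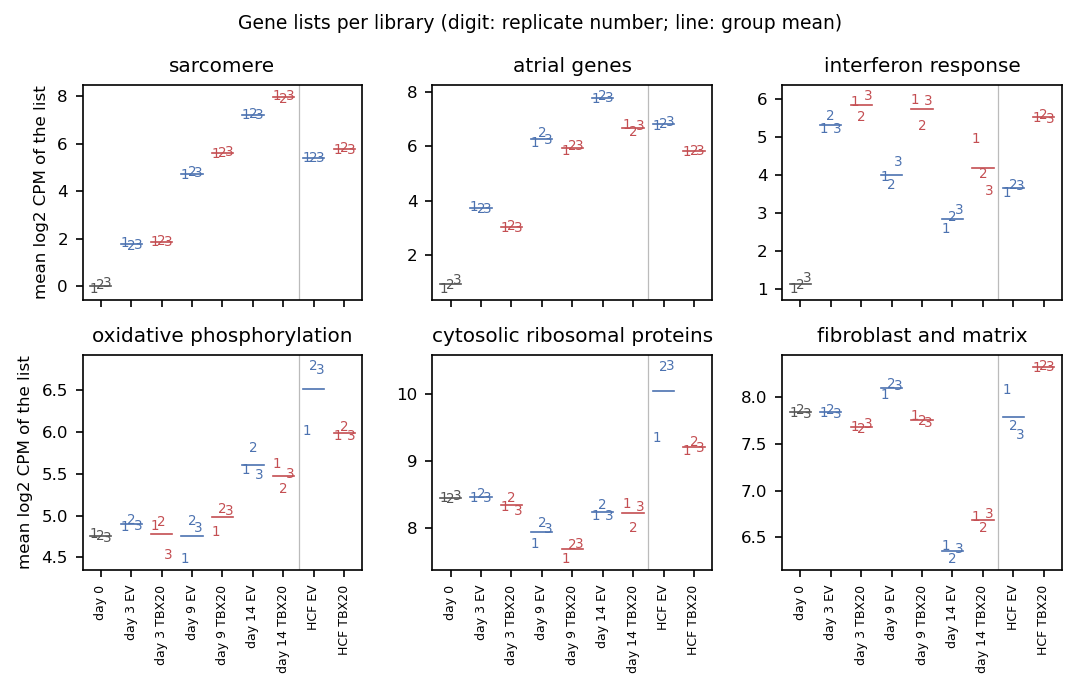
Mean log2 CPM of the sarcomere, atrial, interferon, oxidative phosphorylation, ribosomal protein and matrix lists in each library, by group (digits, replicate numbers; lines, group means). In HCF, EV replicate 1 lay at 6.01 for oxidative phosphorylation, against 6.79 and 6.74 in the other EV libraries and 5.955 to 6.07 with TBX20.

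The 4 TBX20 comparisons share no library, and their calls overlapped more than expected for independent genes in every pair. Genes that move together are not independent, so the p-values of this test can be too small. Among genes tested in both, 1192 rose at both day 9 and day 14 against 346.7 expected, and 1108 fell against 340.8. Between day 14 and HCF, 1317 rose in both against 440 expected and 1223 fell against 510 (Fisher's exact test, one-sided, adjusted p = 6.56e-284 for the falls). Between day 3 and HCF, 488 rose in both against 138.2 expected (adjusted p = 1.96e-176) and 436 fell against 160.9 (adjusted p = 6.03e-105). Opposite calls were no more frequent than chance in any pair (adjusted p = 1). Of 14153 genes tested in all 4, 290 rose and 257 fell in each. The most strongly shared genes besides TBX20 were TNXB and the folate receptor FOLR1 among those that rose. TNXB went by log2 2.89, 3.72, 4.675 and 4.29 at days 3, 9 and 14 and in HCF. For FOLR1 the values were log2 6.01 ± 1.41, 2.97 ± 0.38, 4.78 ± 0.44 and 3.49 ± 0.29, the first being the least certain. Of those that fell, SFRP1, a secreted WNT antagonist, went by log2 −3.04, −4.09, −2.82 and −3.82. GDF5, a growth factor of the BMP family, went by log2 −3.17, −3.68, −4.29 and −3.25, and NTM, a neural adhesion protein, by log2 −3.63, −6.45, −6.66 and −2.99.

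**Figure D4:**
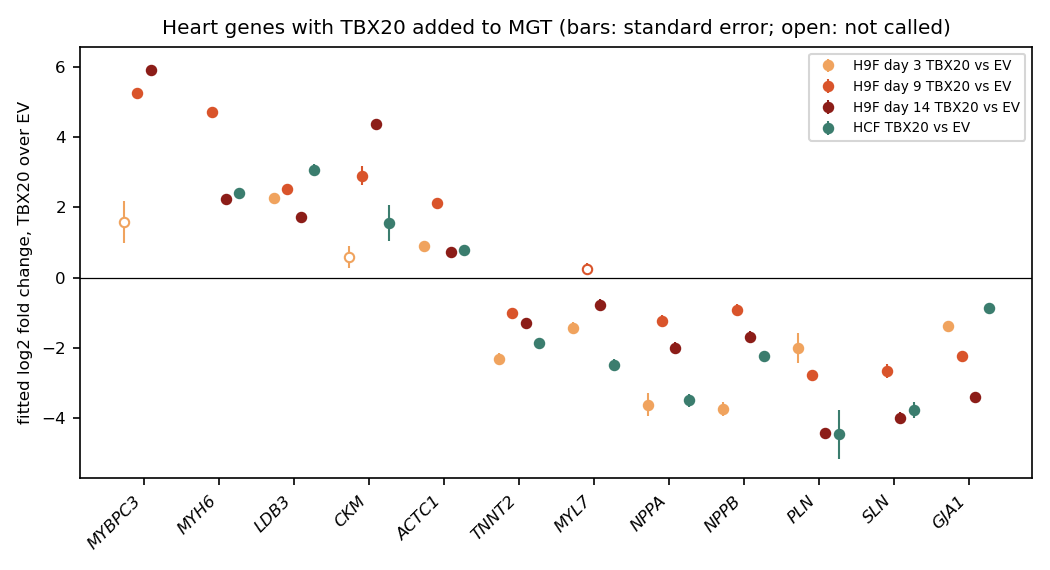
Log2 fold change of heart genes with TBX20 against EV at days 3, 9 and 14 in H9F and in HCF (points, fitted values; open points, not called; bars, SE; n = 3 libraries per group), without MYH6 and SLN at day 3 and MYBPC3 in HCF. PLN was lower by log2 −2.76 ± 0.11 at day 9 and −4.41 ± 0.13 at day 14, and TNNT2 was lower in all 4 comparisons, while LDB3 was higher in all 4.

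The TBX20 effect itself changed between days in H9F. From day 3 to day 9 its log2 value went up for 777 genes and down for 790, and from day 9 to day 14 for 1701 and 1660. The effect on MYBPC3 rose by log2 3.68 ± 0.92 from day 3 to day 9 (adjusted p = 0.0121) and by 0.64 ± 0.16 from day 9 to day 14 (adjusted p = 0.00554). At day 3 the group with fewer MYBPC3 counts held 4, and the effect did not pass (log2 1.58 ± 0.60, adjusted p = 0.151). The size of the first rise is therefore uncertain. The first call ended without day 3 EV replicate 3 (0.596) and the second without day 9 EV replicate 2 (0.0506). For MYH6 it changed by log2 −2.48 ± 0.15 from day 9 to day 14 (adjusted p = 1.4e-11), and EV cells held 2048 ± 123 CPM of it at day 14. The falls of GJA1 deepened at both steps (log2 −0.87 and −1.17), and that of PLN from day 9 to day 14 (log2 −1.65). For TTN and COL1A1 the effect rose by log2 1.135 and 1.12 from day 9 to day 14. The TNNT2 effect changed by log2 1.28 ± 0.20 from day 3 to day 9. Without day 3 TBX20 replicate 3, the effect went down for 494 genes from day 3 to day 9.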

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

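The list tests on the differences between days, the splits of the libraries and the tests that weigh the oxidative phosphorylation patterns and the MGT factor levels, and those on the share of converted cells at days 3 and 14, were chosen after the results were seen. The gene tests of the day differences and the tests on that share at day 9 and in HCF were planned. What set these results apart is a difference of the TBX20 effect between days, which was tested, or between H9F and HCF, which was not.

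The test of the difference itself called 1567 genes between days 3 and 9 and 3361 between days 9 and 14. Among 25 splits drawn of 200 possible, the real one counted, 2 gave as many genes for the first step, the highest other reaching 1880, and 3 for the second, the highest other reaching 3786. Besides the real split, those that called as many (1 and 2) each kept the real groups of 1 day and so that day's effect, and these counts do not decide whether chance can be excluded. Where neither day was kept (19 and 18 splits) the highest count was 0.

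Between days 3 and 9 the genes named for the largest upward change of the TBX20 effect were TLL2 (log2 4.38), MYBPC3 (3.683) and RIMS1 (3.68), and for the downward change PLEKHA7 (−6.129), SFRP5 (−5.852) and BMP6 (−4.974). The TLL2 call ended without day 3 EV replicate 2 (log2 1.58, adjusted p = 0.767), the MYBPC3 call without day 3 EV replicate 3 (0.596) and the BMP6 call without day 3 TBX20 replicate 3 (0.371). MYBPC3 had 4 counts in the day 3 group with fewer, so its day 3 effect was poorly measured. Between days 9 and 14 the named genes were IGF2 (5.911), FAM167A (5.57) and APBB1IP (5.34) on one side and RGS16 (−6.709) and TMEM119 (−6.672) on the other. TMEM119 had no counts with TBX20 at day 14, so its fitted difference is no bound. Genes called in opposite directions with the difference also called numbered 102 between days 3 and 9 and 322 between days 9 and 14. Every opposite call had the difference called, so that condition adds no support, and opposite calls were fewer than chance gives. Between days 3 and 9, 40 rose then fell against 99.39 expected, and 62 fell then rose against 106.9. Between days 9 and 14 these were 158 against 343.2 and 164 against 344.3.

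As lists, the effect between days 3 and 9 differed upward for sarcomere (adjusted p = 2.245e-10), tricarboxylic acid cycle (1.633e-06), interferon (1.241e-06), oxidative phosphorylation (4.742e-06), glycolysis (0.0003307), skeletal muscle (0.0003322), pluripotency (0.01022) and epithelial genes (0.02495), and downward for matrix (0.002347), ribosomal (0.01731) and mitochondrially encoded genes (0.01962). With an estimated correlation sarcomere (0.00364) and skeletal muscle (0.00976) held and the remaining lists gave 0.298 to 0.619. The mitochondrially encoded call ended without day 3 TBX20 replicate 3 (0.105) or day 9 EV replicate 1 (0.221), the epithelial call without day 3 TBX20 replicate 1 (0.0540) or day 9 EV replicate 1 (0.179), and the pluripotency call without day 9 TBX20 replicate 1 (0.0513). The ribosomal call ended without day 3 TBX20 replicate 2 (0.146), day 9 EV replicate 2 (0.171) or 3 (0.05135), or day 9 TBX20 replicate 1 (0.214). Between days 9 and 14 the effect differed downward for oxidative phosphorylation (3.386e-05), tricarboxylic acid cycle (9.7e-06) and atrial genes (0.005111), and upward for matrix (2.46e-09), ribosomal (0.0006945), cell cycle (0.02725) and TGF-beta genes (0.04629). None held with an estimated correlation (0.0963 to 0.554). The TGF-beta call also ended without day 9 EV replicate 2 (0.0905), day 9 TBX20 replicate 2 (0.0677), day 14 TBX20 replicate 1 (0.0512) or day 14 EV replicate 3 (0.0737), and with the replicate block (0.0579).

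Against HCF no difference was tested. Some genes were called in opposite directions, with libraries that did not overlap in either comparison. They numbered 108 for day 3, 298 for day 9 and 203 for day 14. Chance gives a lack of overlap in 10% of genes not chosen by a call. These genes were called in both comparisons, which favours a lack of overlap, so this rule adds no support. Without that rule, opposite calls were fewer than expected in each pair and direction. They ran from 44 against 154.4 expected (higher at day 3, lower in HCF) to 176 against 321.8 (higher at day 9, lower in HCF). Some lists had all TBX20 libraries on one side of EV in H9F and on the other in HCF, given here as TBX20 minus EV in mean log2 CPM. Each value covers the members tested in that cell type, which differ in number for most of these lists. Matrix genes had −0.1537 at day 3 and −0.3395 at day 9 against 0.535 in HCF, cell cycle genes −0.2091 at day 9 against 0.6252, and inflammatory cytokines −0.5298 at day 3 against 0.5687. Smooth muscle markers had 0.3835 at day 3 and 0.1897 at day 9 against −0.321 in HCF, neuronal markers −0.1054 at day 14 against 0.4348, and pacemaker genes −0.6801 at day 14 against 0.815. For neuronal markers the list test pointed upward in both (adjusted p = 0.8716 and 0.3485), so an opposite change is not supported there. Pacemaker genes passed the list test in neither, smooth muscle markers neither at day 9 nor in HCF, and cell cycle genes not at day 9. The list calls that these pairs do hold were lost with an estimated correlation.

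Oxidative phosphorylation genes were lower with TBX20 in HCF, a call lost with an estimated correlation (adjusted p = 0.716) and with fry (0.137). In these libraries, a trend of the fold changes with the joined length of a gene's annotated exons is argued against as the whole cause. The median of the list was −0.5756 ± 0.046 before and −0.4947 ± 0.051 after the trend of the other genes was taken off. Here ± comes from resampling the genes of the list. Genes that move together are not independent, so it does not cover the spread between libraries. The length of the transcripts present was not measured, so a trend with transcript length stays open. A difference among the EV libraries stays open: with EV replicate 1 as the one control the median was −1.2e-05 and the adjusted p 0.7552, but that library's mean log2 CPM of the list (6.011) lies among those with TBX20 (5.955 to 6.066), which fixes this outcome, so the test decides nothing. The call held with any single library left out (2.9e-17 to 8.1e-05). Whether TBX20 lowers these genes in each culture stays open too, since the lowest EV library minus the highest TBX20 library was −0.05435 in mean log2 CPM.

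Oxidative phosphorylation genes were higher with TBX20 at day 9 in H9F, a call lost with an estimated correlation (adjusted p = 0.554) and with fry (0.108). Day 9 EV replicate 1 had the fewest detected genes of its group. Its genes with at least 10 counts numbered 16791, against 16518 and 16671 in its partners, so a lack of low counts is not shown to lower this list. That library as a whole may account for the rise: without it the median log2 fold change went from 0.236 to 0.08446, against 0.1767 to 0.3223 without any other single library. The genes called higher, 15 with all libraries, numbered 8 without it, but also 8 without TBX20 replicate 3 and 9 without TBX20 replicate 2, so their number does not point to that library. A rise of energy metabolism genes stays open, because the tricarboxylic acid cycle list passed without that library (adjusted p = 0.0009555), with 2.4e-05 to 0.347 over its alternatives.

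Atrial genes were called lower at day 3, day 14 and in HCF while members of the sarcomere list rose, but with an estimated correlation the adjusted p was 0.214, 0.291 and 0.452, and without HCF EV replicate 1 the HCF call ended (0.1375). A lower RNA level of the MGT factors is argued against at day 3, where their median log2 fold change was 0.1334, and stays open at day 14 (−0.5921). In HCF the median was 0.1079, but the direction of TBX5 depended on the EV libraries used. It was log2 0.19 without EV replicate 1 and −0.29 with that library as the one control, so the HCF value does not decide this. Another share of converted cells as the whole cause would move the heart genes that rose from day 0 with EV in H9F together, which the counts do not show. These genes came from the sarcomere, calcium handling, atrial and ventricular lists, so their split in part restates the pattern and is no independent test. Of those called, 12 rose and 14 fell at day 3 (46.15% higher), 37 and 22 at day 9 (62.71%), 30 and 23 at day 14 (56.6%, on genes raised by day 9) and 27 and 24 in HCF (52.94%, on genes raised in H9F). A different action of TBX20 on the gene groups stays open, as it was not tested apart from these.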

How the results depend on the processing

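The alternatives that left out the 2 H9F libraries that stood apart, the day 14 libraries or HCF EV replicates 2 and 3, and those that left out each replicate in the list tests, were chosen after seeing the data. Over 739 pairs of a gene and a comparison, 9928 of 10149 gene values under the alternatives kept a call and its direction or were called in neither fit, 129 lost the call, 91 gained it and 1 reversed. TBX5 in HCF, at −0.01, ran from −0.08991 to 0.1867 as replicates were left out, the latter without EV replicate 1 and called. Of 2540 list values, 6 reversed with a call on at least 1 side; changes of direction without a call were not counted. With fry these were calcium handling (6.125e-05) and ventricular genes (6.338e-07) at day 14, matrix (0.01032) and neuronal genes (0.0003941) for EV at day 3, and TGF-beta genes for EV at day 9 (0.0001299), where fry tests a list alone and camera against other genes. Mitochondrially encoded genes in HCF reversed with EV replicate 1 as the one control (0.4784). With the replicate block, genes higher and lower with TBX20 numbered 864 and 947 at day 3, 1960 and 1898 at day 9, 3076 and 3054 at day 14 and 2471 and 2681 in HCF, and the TGF-beta call between days 9 and 14 was lost (0.05787).

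RLE factors, the DESeq2 Wald test, no filter and leaving out mitochondrially encoded genes and factors kept each count of genes within 1.5 times. A fold of at least 2 left 175 higher and 256 lower genes at day 3, 712 and 548 at day 9, 1308 and 920 at day 14, 915 and 850 in HCF, 973 and 1300, 3074 and 2060, and 3924 and 3012 for EV at days 3, 9 and 14, 269 and 188 between days 3 and 9, and 596 and 541 between days 9 and 14. It keeps a subset by construction, and the overlap tests held in 12 of 12 cases. A fit of the compared libraries alone called 1322 lower genes at day 9, and leaving out the 2 H9F libraries that stood apart called 1433 higher genes at day 3; the cause was not tested. As replicates were left out, higher genes at day 3 ran from 540 to 966, higher genes in HCF from 1469 to 4113, lower genes in HCF from 1373 to 3988 and lower genes between days 3 and 9 from 494 to 984, with fewer libraries in each fit. List calls with an estimated correlation numbered 1 at day 3, 3 at day 9, 1 at day 14, 1 in HCF, 0, 4 and 7 for EV at days 3, 9 and 14, and 2 and 0 between days, so 65 were lost. With fry they numbered 19 at day 9, 15 at day 14, 13 and 23 for EV at days 3 and 14, and 12 between days 9 and 14. Small changes were often missed: at 1.5-fold the gene test recovered 50% of simulated changes at day 14 and 22.39% in HCF, with depth not varied.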

Other observations

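The comparison of the TBX20 calls with the course of EV cells from day 0 was planned, and the tests on splits of the libraries were written after the results were seen. The genes in the next paragraph follow the rule for named genes.

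Several list members not described so far also changed with TBX20. SMAD3 and INHBA, both of the TGF-beta pathway, fell by log2 −1.002 and −1.50 at day 3, and TGFBR1 by log2 −1.45 at day 9. At day 14 PDGFRA, a growth factor receptor of mesenchymal cells, and ENG, a co-receptor of the TGF-beta family, rose by log2 2.67 and 2.31, and MYH11, the smooth muscle myosin, fell from 142 to 17.7 CPM. In HCF, THY1, a fibroblast surface protein, rose by log2 2.35, PDK4, which restrains pyruvate oxidation, by log2 2.59, and UCP2, a mitochondrial carrier, fell from 134 to 16.4 CPM. MAP2, a microtubule protein of neurons, rose in all 4 TBX20 comparisons (log2 1.56, 2.08, 1.47 and 1.15). KRT8 rose in all 4 as well (log2 0.60, 1.81, 4.42 and 0.93), and the stem cell-derived and primary cells were not compared directly.

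A hypothesis was that TBX20 moves genes the way they move from day 0 in cells given MGT with EV. Of genes called in both, 56.33% had the same direction for TBX20 at day 3 against EV at day 14 (1644 genes, 53.79% to 56.64% with a library left out) and 57.91% for TBX20 at day 9 (3350 genes, 55.98% to 58.76%), which leaves it open. For TBX20 at day 14 against EV at day 9 the share was 46.75% (4524 genes, 45.56% to 47.46%), and for HCF against EV at day 14 in H9F it was 33.55% (3761 genes, 32.65% to 37.2%). By the limit set beforehand both argue against the hypothesis, the day 14 share only weakly. In the day 14 case every combination of directions exceeded its expected number, so that share weighs little. Lower with TBX20 and higher with EV than at day 0 were 1314 genes against 912.9 expected, and 1095 went the reverse way against 933.5. Higher in both were 1120 against 922.7, and lower in both 995 against 923.5. In HCF, 522 genes were lower in both against 914.7 expected, and 1430 lower with TBX20 and higher with EV than at day 0 against 905.1. HCF is set here against a course measured in other cells.

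For each comparison of 3 libraries with 3, the 10 splits are too few for a share under 0.05, and 1 split, the real one, gave as many genes. The real counts were 1899, 4038, 6328 and 4969 for TBX20 at days 3, 9 and 14 and in HCF, with 0, 1, 1 and 0 as the highest other. For EV at days 3, 9 and 14 they were 7298, 10853 and 12260, with 0, 1 and 0 as the highest other.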
